A study of Mus musculus with 3 samples.

How the data were processed

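Brain cells of 3 libraries were measured by 3' single-cell RNA sequencing: 2 control libraries and 1 VEGF-C/D trap library, each of cells pooled from the hemi-forebrains of 2 mice. Per the labels' protocols, mice were perfused with PBS and heparin, the tissue was dissociated with a Miltenyi Adult Brain Dissociation kit, and libraries were made with 10x Genomics 3' chemistry and sequenced on a NovaSeq. The replicate numbers come from the sample titles, in which the control group has the numbers 1 and 2 and the trap group the number 2.

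The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 6.1.1 per the file headers, on the genome build mm10 per the submitters' processing notes. The same notes name Seurat 4.0.5 with no role. The smallest deposited barcode held 500 UMIs in each library, and no deposited cell annotation was used here. Each file holds 32285 genes. Gene positions were taken from the GRCm38 annotation (GENCODE vM21) by matching gene IDs.

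Total UMIs per library were 110992098 in control 1, 61277011 in control 2 and 74275263 in trap 2. Shares of cells are given with exact (Clopper-Pearson) binomial intervals at 95%, which cover counting error only. Summed UMIs per class ranged from 805998 (OPC-like, trap 2) to 17228000 (oligodendrocyte-like, control 1) over the 5 main classes.

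These choices were fixed before the data were examined: the cell limits, the cluster settings, the marker genes, the gene lists, the tests, the rule for named genes and most of the alternative settings. Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, which left 14224, 9917 and 10269. Scrublet scores (scanpy 1.11.5) were computed per library. Its automatic threshold called no doublets in 2 libraries and 15.8% in control 2, so it was not used. In its place the highest-scoring cells were removed at the usual rate of 0.8% per 1000 cells, which removed 11.4%, 7.94% and 8.22%, a choice made after the scores were seen. Counts were scaled to 10000 UMIs per cell and logged, 2000 variable genes were chosen per library, and cells were clustered on 30 principal components and 15 neighbours (Leiden, resolution 1, leidenalg 0.10.2), with no integration of the libraries.

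Of 42 clusters, 19 stayed unnamed. A cluster was given the name of a class when at least 75% of the class's markers, and at least 3, were at least 2-fold above the mean of the other clusters (with 20 CPM added to both) and at 20 CPM or more. It stayed unnamed when at least 1 in 3 of the markers of an unrelated class, and at least 3, passed too. Where both of a related pair passed, such as new and mature oligodendrocytes, 1 of them, set in the rule, gave the name (in this example the new oligodendrocytes). These limits of the naming rule were set after the clusters were seen. Class names are rebuilt from markers, so they are written as "-like", and they may differ from names the submitters used. Most unnamed clusters carried the markers of 2 classes, as doublets do, and these clusters may hold doublets that were not removed. The median doublet score was 0.148 in cluster 11, of oligodendrocyte and microglia markers, against 0.049 in oligodendrocyte-like cluster 0 and 0.039 in microglia-like cluster 1. The cluster named from haemoglobin was not compared, because it held 40, 35 and 27 cells, under the limit of 50 given below. Only 12.5%, 14.3% and 25.9% of its cells held a haemoglobin UMI. In the oligodendrocyte-like class, cluster 4 was led by Anln and Klk6.

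Counts were summed per library and class. For each class with at least 50 cells in every library, trap and control were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. This limit was applied at the usual settings only. Under other settings a class could hold fewer cells, as microglia-like cells of trap 2 did at a mitochondrial maximum of 5%. The fit has 1 residual degree of freedom, from the 2 controls, so the lone trap library is assumed to vary like them. The prior degrees of freedom were 9.42 in oligodendrocyte-like, 30.7 in OPC-like, 17.2 in astrocyte-like and 21.5 in endothelial-like cells and infinite in microglia-like cells. The prior degrees of freedom were also infinite in border macrophage-like, mural-like, ependymal-like and choroid plexus-like cells. Where they are infinite, the test uses the spread estimated across genes and gives no weight to a gene's own spread. The labels give pools and not single mice, so no p-value measures the spread between mice. The spread between pools enters the gene tests only as moderated across genes. Interaction tests used the library as a block. Shares were compared by a two-sided exact permutation test over the 3 libraries. CPM values are scaled by TMM factors.

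The genes named in each main class were those with an adjusted p under 0.05, a trap value outside both controls and a mean log2 CPM of at least 5, at most 10 per direction. To these were added the 4 members with the smallest p of each called list, the 3 most abundant members of 5 lists whatever their p, and Vegfc, Vegfd, Flt4 and Kdr. Of the genes this rule names, 2 are not reported here. Gene lists with at least 5 tested genes were tested by camera (limma 3.58.1) with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over 146 tests of lists and classes. Lists of marker genes of other cells were read only in classes other than their own.

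On simulated counts with 200 changed genes, the test recovered 64% of 2-fold and 90% of 4-fold changes in oligodendrocyte-like cells (14268 genes), 22% and 73% in OPC-like (10790), 67% and 90% in astrocyte-like (14802), 54% and 88% in microglia-like (14033) and 63% and 83% in endothelial-like cells (12696). Of the simulated calls 6.67%, 5.94%, 4.85%, 2.74% and 4.58% were false. Of 24 unchanged lists per class, camera called none. These error rates hold for the simulated counts and need not hold for the measured ones. There the gene test also made calls with a control as the lone library. The list calls of camera on the measured counts were lost with an estimated correlation.

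The alternatives tried were scaling by DESeq2 size factors or library totals, no gene filter or a mean of at least 20 CPM, doublets kept, a mitochondrial maximum of 5%, a minimum of 1000 UMIs, counts thinned to the smallest library, genes of free RNA left out, DESeq2 1.42.0 (Wald test), limma-voom, resolutions of 0.5 and 2, shares of the cells without microglia-like cells, and each control left out. Alternatives chosen after seeing the data were a doublet number set from all deposited barcodes, a mitochondrial maximum of 20%, these resolutions for the gene tests, a denominator without unnamed clusters, microglia cluster 1 alone, the class without cells of at least 10 haemoglobin UMIs, and all alternatives of the interaction tests and of the less frequent classes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.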

Results

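Forebrain cells of 13-week-old male C57BL/6J mice were profiled by droplet-based single-cell RNA sequencing 5 weeks after the start of treatment. Mice had received intraperitoneal injections of an AAV9 vector, a virus that carries a transgene to many tissues, at weeks 0 and 3. The VEGF-C/D trap vector encodes the ligand-binding part of mouse VEGFR-3 fused to an immunoglobulin part, a secreted protein that captures the lymphatic growth factors VEGF-C and VEGF-D. The control vector encodes a part of the same receptor that does not bind them. The comparison asks how capture of VEGF-C and VEGF-D, on which the lymphatic vessels of the meninges depend, changes brain cells, oligodendrocytes among them. There were 2 control libraries (control 1 and control 2) and 1 trap library (trap 2), each made from cells pooled from the hemi-forebrains of 2 mice, so the libraries are separate pools. Whether the injected transgenes were expressed was not checked here, because 3' reads mapped to the mouse genome check nothing about a soluble receptor.

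The deposited counts held 36257 barcodes in control 1, 18665 in control 2 and 31154 in trap 2, with 110992098, 61277011 and 74275263 UMIs in total. Median UMIs per barcode were 2143, 2453 and 1861. The median mitochondrial share was 12.2% in control 1, 9.31% in control 2 and 12.9% in trap 2. After filtering and doublet removal, 12605, 9130 and 9425 cells were kept, with a median of 4218, 3861.5 and 3503 UMIs and a median mitochondrial share of 7.15%, 6.31% and 7.63%. The trap library was the shallowest per kept cell and had the highest mitochondrial share.

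The same major cell classes were present in all 3 libraries, and the most frequent named classes in the controls were oligodendrocyte-like, astrocyte-like, microglia-like and endothelial-like cells. In trap 2 neuron-like cells (812) outnumbered endothelial-like cells (736). Neuron-like cells made up 8.62% of kept cells in trap 2 (95% exact binomial interval 8.06 to 9.20), against 4.49% (4.14 to 4.87) in control 1 and 4.41% (4.002 to 4.86) in control 2. Ependymal-like cells, which line the ventricles, made up 1.81% (1.55 to 2.10) in trap 2, against 0.777% and 0.953% in the controls. Choroid plexus-like cells, the epithelium that secretes cerebrospinal fluid, made up 0.976% (0.788 to 1.20) in trap 2, against 2.32% (2.07 to 2.60) and 1.79% (1.52 to 2.08). Microglia-like cells, the resident phagocytes of the brain, made up 12.1% (11.5 to 12.8) in trap 2, against 14.7% (14.0 to 15.3) in control 1 and 21.7% (20.8 to 22.5) in control 2. Their log2 ratio of -0.58 was -0.12 at a mitochondrial maximum of 20% and -2.50 at 5%.

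For the neuron-like, ependymal-like and choroid plexus-like shares the trap value lay outside both control values by more than the controls differed, with an exact two-sided permutation p of 0.333. That is the smallest p that 3 libraries can give, so no share could pass a 0.05 threshold. Intervals cover counting error only and not the differences between pools of mice. The shares of unnamed clusters were 20.3%, 12.5% and 20.7%, which moves every other share.

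**Figure D1:**
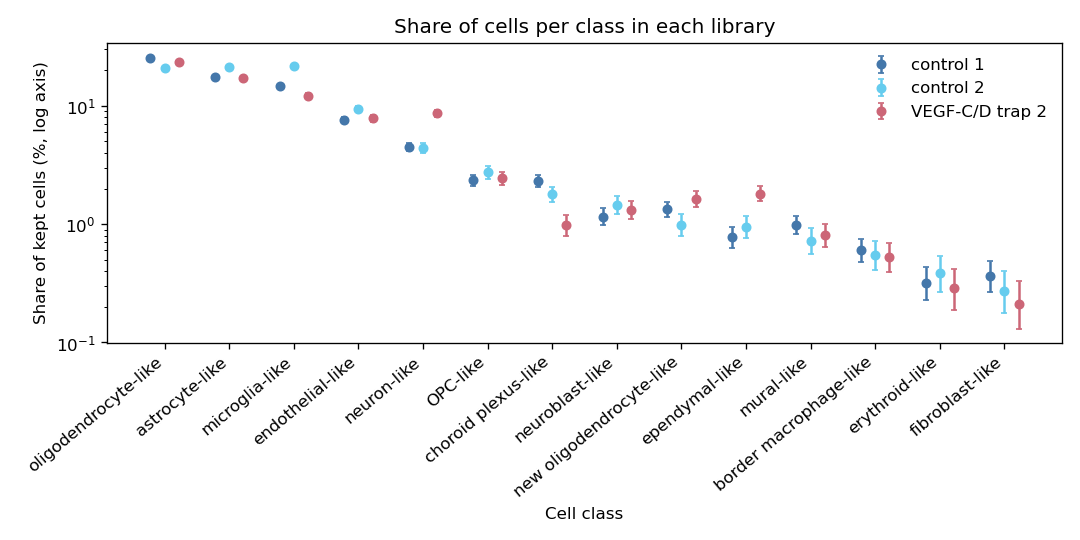
Share of kept cells per class (vertical axis in percent, logarithmic) in control 1, control 2 and VEGF-C/D trap 2, with points for the share and bars for the 95% exact binomial interval. Neuron-like cells stood at 8.62% in the trap library against 4.49% and 4.41% in the controls, and choroid plexus-like cells at 0.976% against 2.32% and 1.79%.

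Oligodendrocyte-like cells, which carry myelin genes such as Mbp, made up 23.6% (22.8 to 24.5) of kept cells in trap 2, between 25.3% (24.5 to 26.0) in control 1 and 21.0% (20.2 to 21.9) in control 2. The precursors, OPC-like cells, stood at 2.44% in trap 2, also between the controls at 2.34% and 2.75%. The log2 ratios of 0.03 and -0.06 turned to -0.49 for oligodendrocyte-like cells at a mitochondrial maximum of 5% and to 0.57 for OPC-like cells with doublets kept. New oligodendrocyte-like cells, the stage between both, stood at 1.63% (1.39 to 1.91) in trap 2, against 1.33% (1.14 to 1.55) and 0.986% (0.793 to 1.21). Within the lineage alone, mature cells made up 85.3% in trap 2, against 87.3% and 84.9%, and OPC-like cells 8.81%, against 8.09% and 11.1%. New oligodendrocyte-like cells made up 5.90% (5.02 to 6.87) of the lineage in trap 2, against 4.61% (3.95 to 5.34) and 3.98% (3.22 to 4.87), with an exact permutation p of 0.333. The intervals of trap 2 and control 1 overlapped for this share. The log2 ratio of trap to control was 0.46, and it was 0.0947 at a mitochondrial maximum of 20% and 1.08 at 5%.

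In oligodendrocyte-like cells the metallothionein genes Mt2 and Mt3, whose proteins bind zinc and copper, were higher in the trap library. Mt2 stood at 115 TMM-scaled CPM in trap 2 against 63.5 ± 3.44 in the controls (SD, n = 2), a log2 change of 0.86. Mt3 stood at 390 against 223 and 193, a log2 change of 0.90. Transthyretin, Ttr, a transport protein made by the choroid plexus, stood at 354 in trap 2 against 626 and 709, a log2 change of -0.92. Myelin genes and cholesterol synthesis genes differed little: Mbp stood at 4163 in trap 2 against 4021 and 4277 and Hmgcs1 at 200.4 against 200.3 and 197.

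edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5 of 14536 genes, 4 higher and 1 lower, and 1124 genes had an unadjusted p under 0.05. The long noncoding RNA gene 7630403G23Rik (ENSMUSG00000098758, GRCm38 chromosome 9, 34042369 to 34059019) had a log2 change of 0.86 ± 0.10 (SE) and an adjusted p of 0.0378. Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) had a standard error of 0.11 and the same adjusted p, and it overlaps the annotated gene Gm45774, so its counts are uncertain to that extent. Mt3 (ENSMUSG00000031760, chromosome 8, 94152607 to 94154146) and Hmgb2, which encodes a chromatin protein, also had an adjusted p of 0.0378. Hmgb2, below the abundance limit of the rule for named genes and chosen after its values were seen, stood at 34.2 CPM in trap 2 against 11.7 and 15.1. Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321) had an adjusted p of 0.0422. Ttr UMIs were in 73.9% of oligodendrocyte-like cells in trap 2, against 94.5% and 96.9% in the controls, and in microglia-like cells, which also should lack the gene, in 75.2% against 95.2% and 96.5%.

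Of the myelin list, 0 of 15 measured genes passed in oligodendrocyte-like cells over all genes tested by edgeR, and 0 when adjusted over the list alone. None of them had an unadjusted p under 0.05 (0 of 15), and DESeq2 and limma-voom called 0. The median log2 change of the list was 0.03, 9 of its 15 genes lay above 0, and camera's adjusted p was 0.980. The cholesterol synthesis list likewise had 0 of 24 calls by edgeR, DESeq2 and limma-voom, 0 genes with an unadjusted p under 0.05, a median of -0.03 and 11 genes above 0, with a camera adjusted p of 0.840. Among the disease-associated oligodendrocyte genes, 2 were called higher and 1 lower of 14 when adjusted over the list alone, and Mt2 was the 1 call over all genes tested. The interferon response list (20 genes, median 0.11, camera adjusted p = 0.571) and the MHC class I list (9 genes, median -0.11, camera adjusted p = 0.507) were not called.

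camera with a preset correlation of 0.01 called 8 lists in these cells. The mitochondrial genome list had 13 of 13 genes above 0, a median of 0.28 and an adjusted p of 8.90e-10, with 7 genes higher when adjusted over the list alone. Over all genes edgeR, DESeq2 and limma-voom each called 0 of its genes, and 7 had an unadjusted p under 0.05. mt-Nd3 stood at 2137 CPM in trap 2 against 999 and 1545. Markers of other cells moved in the same library: the neuron list had 8 of 8 genes above 0 (median 0.55, 6 higher when adjusted over the list alone), and the haemoglobin list 4 of 5 (median 2.51, 4 higher). The choroid plexus list had 2 genes lower when adjusted over the list alone, Ttr and Folr1, with a median of -0.10. The astrocyte, homeostatic astrocyte and OPC identity lists were called up with medians of 0.23 (-0.00446 without control 2), 0.20 and 0.30, and the disease-associated microglia list down with a median of -0.10. The call of each of these 8 lists was lost with an estimated correlation, where the adjusted p was 0.959.

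**Figure D2:**
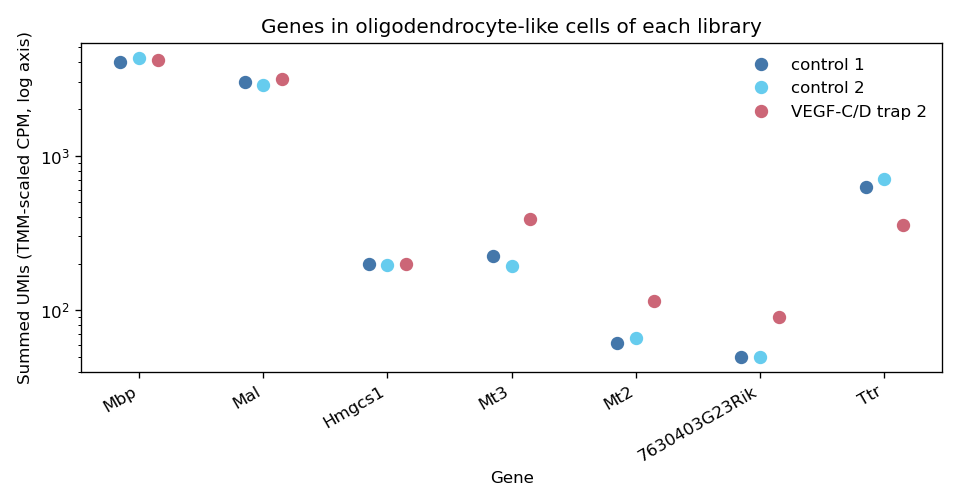
Summed UMIs of 7 genes in oligodendrocyte-like cells (vertical axis in TMM-scaled CPM, logarithmic), 1 point per library. Mt3 stood at 390 in the trap library against 223 and 193, Ttr at 354 against 626 and 709, while Mbp, Mal and Hmgcs1 lay near or between the controls.

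The 5 calls in oligodendrocyte-like cells should be read beside the same test with each control as the lone library: control 1 against the other libraries gave 10 calls and control 2 gave 32. With doublets set from all deposited barcodes the count was 83, and with a minimum mean of 20 CPM edgeR called 0, where 487 genes had an unadjusted p under 0.05. DESeq2 called 5 and limma-voom 7 without that minimum.

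In OPC-like cells 11 of 11231 genes were called, 9 higher and 2 lower. Ttr, of the choroid plexus list, stood at 392 CPM in trap 2 against 1173 and 1054, and Chst9, a sulfotransferase gene, at 59.2 against 149 and 152. Higher in trap 2 were Grin2a, an NMDA receptor subunit gene (66.7 against 14.9 and 15.3 CPM), Kcnip4, a potassium channel partner gene (299.9 against 134.8 and 134.4), and the ribosomal gene Rps27 (643 against 310.1 and 347). Grin2a and Kcnip4 are also among the leading genes of neuron-like cluster 8. That cluster held 5.00% of kept cells in trap 2, against 2.83% and 1.95% in the controls. Whether neuronal RNA gave these 2 changes was not tested. Atp10a, a lipid-transporting ATPase gene that is also among the leading genes of an endothelial cluster, stood at 217 against 86.0 and 36.7.

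By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 changes were -1.50 ± 0.20 for Ttr (SE, adjusted p = 2.12e-04), -1.34 ± 0.27 for Chst9 (0.0274), 2.14 ± 0.35 for Grin2a (0.00281), 1.16 ± 0.22 for Kcnip4 (0.0152) and 0.97 ± 0.20 for Rps27 (0.0274). Without control 1 the log2 change of Atp10a was 2.54 and without control 2 it was 1.33, against 1.79 with both. Crip1 (1.57), Slc24a2 (1.26) and Slc6a6 (1.24), a taurine transporter gene, were also higher, and for Slc6a6 the values without control 1 and without control 2 were 1.79 and 0.85. Of the trap UMIs of Grin2a, 17 of 54 came from 1 cell, and of Kcnip4 35 of 243. The remaining calls below the abundance limit were Acta2, with 17 of its 40 trap UMIs in 1 cell, and 9330111N05Rik, with 13 of 40; both were chosen after their values were seen.

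camera called 14 lists in OPC-like cells. The OPC identity list was down, with 0 of 11 genes above 0, a median of -0.44 and an adjusted p of 4.33e-07; 1 gene was lower when adjusted over the list alone. Over all genes edgeR, DESeq2 and limma-voom each called 0 of them, and 8 had an unadjusted p under 0.05. Pdgfra, the growth factor receptor gene of these precursors, stood at 602 CPM in trap 2 against 685 and 1060. The endothelial marker list was up in 7 of 7 genes (median 1.06, 7 higher when adjusted over the list alone), as was the list of endothelial barrier and transport genes in 16 of 17 (median 0.79, 7 higher). Slco1a4 stood at 519.6 CPM against 353 and 140.5, and Ly6c1 at 312 against 198.5 and 76.4, so control 2 was the library furthest from the others. The interferon response (median 0.96), immediate early gene (0.72), MHC class I (0.72), reactive astrocyte (0.67), angiogenic endothelial (0.60), VEGF ligand and receptor (0.54) and disease-associated oligodendrocyte (0.54) lists were up in the same cells. In the VEGF list 4 of 7 genes lay above 0. Without TMM scaling, Flt1 stood at 756 CPM in trap 2 against 633 in control 1 and 241 in control 2. Kdr stood at 49.9 against 51.8 and 14.0, and Flt4 at 8.52 against 8.90 and 7.98. These 3 receptor genes were thus lowest in control 2, while Vegfc and Vegfa were lowest in control 1 and Vegfd in trap 2. Of the interferon response, angiogenic endothelial and VEGF lists edgeR called 0 of 18, 0 of 11 and 0 of 7 genes over all genes and when adjusted over the list alone. Of these genes 6, 2 and 1 had an unadjusted p under 0.05, DESeq2 called 0, and limma-voom 0, 0 and 1. The interferon genes Ifitm3 and Oasl2 had log2 changes of 1.76 and 3.45 without control 1 and of 0.44 and 1.01 without control 2. The myelin and oligodendrocyte marker lists (both 0.28), the mitochondrial genome list (0.22, 13 of 13 above 0) and the cytosolic ribosome list (0.07, 19 of 30 above 0) were up too. Without control 2 the median of the list myelin in OPC-like cells turned to -0.0283 and the median of the list cytosolic ribosome in OPC-like cells to -0.00863. The calls of all 14 lists were lost with an estimated correlation (adjusted p = 0.959). With control 2 as the lone library the gene test made 229 calls in these cells and with control 1 it made 8. At a mitochondrial maximum of 20% edgeR called 0, where 502 genes had an unadjusted p under 0.05; DESeq2 and limma-voom, run at 10%, called 1 and 67.

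In astrocyte-like cells 37 of 15100 genes were called, 32 higher and 5 lower. Besides Ttr, the lower genes were Agt, which encodes angiotensinogen (139 CPM in trap 2 against 205 and 254), Tafa1, a secreted factor gene (44.1 against 73.6 and 75.0, reversed to a log2 change of 0.54 at a mitochondrial maximum of 5%), Angpt1, which encodes a ligand of the endothelial receptor Tie2 (39.7 against 61.5 and 72.9), and Nxn, a redox protein gene (103 against 155 and 156). The higher genes included Slc43a2, an amino acid transporter gene (83.4 against 42.3 and 37.2), Hmgb2 (64.8 against 23.98 and 32.6), Arrdc3 (log2 change 0.85) and the ribosomal genes Rps29 (1554 against 896 and 962), Rpl35, Rpl38 and Rps28. Of the glutamate transporter genes, Slc1a2 stood at 7366 against 8363 and 7455 and Slc1a3 at 3362 against 2906 and 2987. Of the gap junction genes, Gja1 stood at 1330 against 1394 and 1567 and Gjb6 at 254 against 296 and 327, and none of these 4 genes was called.

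The log2 changes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were -0.72 ± 0.13 for Agt (SE, adjusted p = 0.0227), -0.75 ± 0.13 for Tafa1 (0.0176), -0.76 ± 0.15 for Angpt1 (0.0362), -0.59 ± 0.12 for Nxn (0.0436) and -1.08 ± 0.12 for Ttr (2.78e-04). They were 1.06 ± 0.13 for Slc43a2 (7.93e-04), 1.20 ± 0.16 for Hmgb2 (0.00206) and 0.74 ± 0.11 for Rps29 (0.00246). Agt leads astrocyte cluster 3, which held 38.8% of astrocyte-like cells in trap 2 against 43.8% and 48.0% in the controls. The haemoglobin gene Hba-a1 was called with a log2 change of 2.74, which was 5.53 without control 1 and 1.84 without control 2. S100a9, called below the abundance limit and named after its values were seen, had 49 of its 50 trap UMIs in 1 cell.

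camera called 7 lists in astrocyte-like cells. The mitochondrial genome list was up with 13 of 13 genes above 0 and a median of 0.26, and 6 of its genes were higher when adjusted over the list alone, with mt-Nd3 and mt-Atp8 called over all genes. The cytosolic ribosome list was called up while its median was -0.01 (0.0623 without control 1), with a mean of 0.10: 3 of 30 genes were higher over all genes and 5 when adjusted over the list alone. The homeostatic astrocyte list was called down with a median of -0.15 and 3 of 15 genes above 0, and no member passed over all genes or when adjusted over the list alone by edgeR. DESeq2 and limma-voom called 0 members, and 3 had an unadjusted p under 0.05. The neuron list was up (8 of 8, median 0.44), the haemoglobin list up (median 2.21), the choroid plexus list down (0 of 7, median -0.91) and the microglia list down (median -0.15). All 7 calls were lost with an estimated correlation (adjusted p = 0.959). The gene count was 11 with control 1 and 13 with control 2 as the lone library, 5 with doublets set from all barcodes, and 21 without the cells that held at least 10 haemoglobin UMIs.

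In microglia-like cells 114 of 14355 genes were called, 108 higher and 6 lower. The genes with the smallest p were the haemoglobin genes of red blood cells: Hbb-bs stood at 497 CPM in trap 2 against 91.1 and 6.02, and Hba-a1 at 209 against 29.3 and 1.95. Both turned lower with doublets set from all deposited barcodes (log2 changes of -0.65 for Hbb-bs in microglia-like cells and -0.49 for Hba-a1 in microglia-like cells) and at a mitochondrial maximum of 5% (-4.52 and -3.00). At that maximum trap 2 kept fewer than 50 microglia-like cells. Mt3 (603 against 344 and 294) and Mt2 (152 against 81.5 and 74.2) were higher here too. Also higher were Dpp10 (73.9 against 30.5 and 31.1), Csmd1 (73.9 against 35.1 and 35.0) and Syt1, of the neuron list (137 against 85.0 and 67.0). Of the trap UMIs, 35 of 203 of Dpp10 and 32 of 145 of Tenm2 came from 1 cell, and Csmd1 in microglia-like cells turned to -7.67 at a mitochondrial maximum of 5%. The microglial genes Cx3cr1 (3403 against 3270 and 3816) and Csf1r (1874 against 1863 and 2213) differed by less than the controls did.

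By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 changes were 0.92 ± 0.12 for Mt3 (SE, adjusted p = 2.73e-10), 0.96 ± 0.13 for Mt2 (1.47e-09), 1.26 ± 0.17 for Dpp10 (5.76e-10) and 1.08 ± 0.17 for Csmd1 (3.10e-07). Tenm2 (1.00), Rorb (0.90) and Snhg11 (0.90, but -0.40 at a mitochondrial maximum of 5%) were higher as well. Rorb is among the leading genes of astrocyte-like cluster 2, Snhg11 of neuron-like cluster 19 and Dpp10 of neuron-like cluster 31. Lower were Ttr (-0.89), AU020206 (-0.48, adjusted p = 0.0371) and Enpp2 (-0.54, adjusted p = 0.0171), which encodes autotaxin and belongs to the choroid plexus list. The log2 changes of Hbb-bs and Hba-a1 were 3.37 and 3.76, both 6.15 without control 1, and 2.44 and 2.79 without control 2. Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical copies, so the split of counts within each pair is uncertain. In trap 2, 4 microglia-like cells with at least 10 haemoglobin UMIs held 98.1% of the haemoglobin UMIs of this class. Cluster 6, which has more UMIs per cell than cluster 1, held 434 and 591 microglia-like cells in the controls and 90 in trap 2, while cluster 1 held 1413, 1387 and 1052.

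camera called 9 lists in microglia-like cells. The homeostatic microglia list was not called (14 genes, median -0.07, 2 above 0, adjusted p = 0.151), nor was the disease-associated microglia list (22 genes, median -0.12, adjusted p = 0.143). The mitochondrial genome list was up in 13 of 13 genes (median 0.32, 4 higher when adjusted over the list alone and 3 over all genes). The neuron list was up with a median of 0.55 and 5 of 8 genes called, OPC identity with 0.51 and 3 of 11 called, and the astrocyte list with 0.30 and 2 of 7 called. The MHC class II list was called up with a median of 0.84, 3 genes higher and 1 lower when adjusted over the list alone, from 14 trap UMIs of H2-Aa and 10 of H2-Eb1. The homeostatic astrocyte (0.18), oligodendrocyte marker (0.24) and haemoglobin (3.72) lists were up and the choroid plexus list (-0.37) was down. All 9 calls were lost with an estimated correlation (adjusted p = 0.959). With control 2 as the lone library the gene test made 70 calls and with control 1 it made 2; in cluster 1 alone it made 30. The Wald test of DESeq2 called 0 genes in the whole class, where 90 had an unadjusted p under 0.05, and limma-voom called 62.

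In endothelial-like cells 6 of 13006 genes were called, 5 higher and 1 lower. The haemoglobin genes changed most, with Hbb-bt at 211 CPM in trap 2 against 24.05 and 3.58 and Hba-a1 at 497 against 96.0 and 26.7. Fmo2, which encodes a flavin monooxygenase, stood at 140.4 against 69.2 and 84.5, and Ttr, of the choroid plexus list, at 318 against 683 and 894. Of the barrier and transport genes, Cldn5 lay below both controls (2028 against 2372 and 2371) and was not called (log2 change -0.23), and Bsg (4440 against 4352 and 4655) and Slco1a4 (3234 against 3404 and 3221) lay between them. Of the captured ligands, Vegfc stood at 53.2 against 76.2 and 69.1 and Vegfd at 30.002 against 29.04 and 22.03, and of their receptors Flt4, the gene of VEGFR-3, stood at 62.5 against 73.7 and 65.3 and Kdr at 479 against 554 and 486.

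By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Fmo2 had a log2 change of 0.87 ± 0.15 (SE) and an adjusted p of 0.0139, and Ttr of -1.31 ± 0.16 and 1.24e-04. Hbb-bt had a log2 change of 3.86 ± 0.32 and an adjusted p of 3.86e-07, with 5.54 without control 1 and 3.08 without control 2. The changes of Hba-a1 (2.99), Hba-a2 (2.83) and Hbb-bs (2.82) were 4.17, 4.05 and 4.48 without control 1 and 2.36, 2.19 and 2.07 without control 2. Without the cells of at least 10 haemoglobin UMIs, Hbb-bs in endothelial-like cells turned to -0.0408, and 12 genes were called, of which 2 were among these 6. Vegfc (chromosome 8, 54077606 to 54187096) had a log2 change of -0.45 ± 0.17 that did not pass (adjusted p = 0.920), and Vegfd, Flt4 and Kdr had 0.22, -0.16 and -0.12, each with an adjusted p of 0.996. In trap 2, 13 endothelial-like cells with at least 10 haemoglobin UMIs held 99.3% of the haemoglobin UMIs of this class.

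camera called 8 lists in endothelial-like cells. The endothelial activation list was called up with a median of 0.29, and 3 of its 6 genes were higher when adjusted over the list alone. Over all genes edgeR and DESeq2 called 0 of the 6 and limma-voom 1, and 3 had an unadjusted p under 0.05. Vcam1, an adhesion molecule gene, stood at 91.1 CPM in trap 2 against 57.2 and 47.1. The mitochondrial genome list was up in 13 of 13 genes (median 0.23), the neuron list in 7 of 8 (0.28) and the haemoglobin list in 5 of 5 (2.83). The choroid plexus (-0.68), microglia (-0.20), homeostatic microglia (-0.09) and p53 and apoptosis (-0.08) lists were down. Of the microglia list edgeR called 0 of 7 genes and of the p53 and apoptosis list 0 of 13, over all genes and when adjusted over the list alone, as did DESeq2 and limma-voom over all genes. Of these genes 3 and 2 had an unadjusted p under 0.05. All 8 calls were lost with an estimated correlation (adjusted p = 0.959). The lists of barrier and transport genes (18 genes, median 0.01), VEGF ligands and receptors (10 genes, -0.11) and angiogenic endothelial genes (11 genes, -0.10) were not called, with adjusted p of 0.695, 0.364 and 0.285. With control 1 as the lone library the gene test made 120 calls and with control 2 it made 0, where 551 genes had an unadjusted p under 0.05. With doublets kept, edgeR called 0 between trap and controls, where 558 genes had an unadjusted p under 0.05. DESeq2 and limma-voom were not run on these 2 settings, and with doublets removed they called 1 and 12.

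In the less frequent classes 330 genes were called in all, 198 of them in ependymal-like and 123 in mural-like cells. The mural-like class was 1 cluster, led by the smooth muscle genes Acta2, Tagln and Myh11, while 2 clusters led by pericyte genes such as Vtn and Abcc9 stayed unnamed. In it 96 genes were higher and 27 lower, and 11 of 15 myelin genes were called higher, with a median log2 change of 1.64. In ependymal-like cells 165 were higher and 33 lower, and 11 of the 15 myelin genes were called, with a median of 1.04. The median doublet score was 0.132 in the mural-like and 0.104 in the ependymal-like cluster, against 0.049 in the first oligodendrocyte-like cluster. At resolution 0.5 the mural-like count was 26, and with doublets kept the ependymal-like count was 67. In border macrophage-like cells Hbb-bs, Car4, Ptprb and Itga1 were higher, and in choroid plexus-like cells Cxcl12 and Mt2 were higher and Siglech and Agbl4 lower. Ptprb and Cxcl12 are among the leading genes of endothelial-like clusters 7 and 5, Itga1 of unnamed cluster 9 and Siglech of microglia-like cluster 1. The endothelial marker Flt1, not among the calls, stood at 827 CPM without TMM scaling in border macrophage-like cells of trap 2, against 465 and 466. Whether RNA of other cells gave these calls was not tested. Rad51c was the 1 call in neuroblast-like cells, at 365 CPM against 3.55 and 17.0. At a minimum of 1000 UMIs per cell edgeR called 0 genes there, where 209 had an unadjusted p under 0.05 (at 500 UMIs DESeq2 called 0 and limma-voom 1), and with doublets kept and at a mitochondrial maximum of 20% it was not among the calls. The named genes of these classes were chosen after their values were seen.

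No gene was called in new oligodendrocyte-like or neuron-like cells by edgeR's quasi-likelihood test, with 368 of 10037 and 619 of 14472 genes at an unadjusted p under 0.05. DESeq2 called 0 in both, and limma-voom 1 and 0. Other settings of edgeR gave calls: in new oligodendrocyte-like cells 37 with doublets set from all deposited barcodes, 20 at resolution 2 and 13 with library totals, and in neuron-like cells 55 and 28 at mitochondrial maxima of 20% and 5% and 30 without a gene filter. The mural-like and ependymal-like counts with control 2 as the lone library were 51 and 20, and with control 1 both were 0 by edgeR, where 98 and 311 genes had an unadjusted p under 0.05; DESeq2 and limma-voom were not run on these splits. In border macrophage-like, neuroblast-like, neuron-like and new oligodendrocyte-like cells, control 2 as the lone library gave more calls than trap 2. In choroid plexus-like, neuroblast-like and neuron-like cells control 1 as the lone library did, with its largest count in neuroblast-like cells. The Wald test of DESeq2 called 9 genes over the less frequent classes and with a minimum mean of 20 CPM edgeR called 186.

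The difference between trap 2 and the controls in oligodendrocyte-like cells was compared with that in the other main classes by a test of the interaction. S100a5, which encodes a calcium-binding protein, had a log2 difference higher by 3.26 ± 0.36 (SE) in oligodendrocyte-like than in astrocyte-like cells, with an adjusted p of 1.90e-13 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of its 257 trap UMIs in oligodendrocyte-like cells 94 came from 1 cell, and the controls had 5 and 57 UMIs. Tenm2, a synaptic adhesion gene, and Grm7, a glutamate receptor gene, differed in this way by -1.11 and -1.35 log2 between oligodendrocyte-like and astrocyte-like cells. Tenm2 also differed from microglia-like cells by -1.24 and from endothelial-like cells by -1.26, and Hmgb2 by 0.99 and 1.07. From 1 cell came 25 of the 229 trap UMIs of Tenm2 in astrocyte-like, 32 of 145 in microglia-like and 22 of 119 in endothelial-like cells. In all, 38 genes differed from astrocyte-like cells, 25 with the higher log2 difference in oligodendrocyte-like cells and 13 with the lower. From microglia-like cells 14 differed (4 and 10), and from endothelial-like cells 9 (4 and 5). With doublets kept these counts were 0, 1 and 4 by edgeR, and in the first 636 genes had an unadjusted p under 0.05; no other tool was run on the interaction.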

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

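Among the tests below, the share of cells with a haemoglobin UMI, the comparison of short genes between the controls and at a mitochondrial maximum of 5%, and the change that the mix of astrocyte clusters alone gives were chosen after the result was seen.

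The difference between trap 2 and the controls was not the same in oligodendrocyte-like and astrocyte-like cells for 38 genes by an interaction test, with S100a5, Tenm2 and Grm7 first. It differed between oligodendrocyte-like and microglia-like cells in 14 genes, with Hbb-bt, Tenm2 and S100a5 first, and between oligodendrocyte-like and endothelial-like cells in 9 genes, with S100a5, Hbb-bt and Tenm2 first. S100a5 had 5 UMIs in oligodendrocyte-like cells of control 1, 57 in control 2 and 257 in trap 2, and in astrocyte-like cells 2, 107 and 37.

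A cluster left without a name, number 15, lay outside the compared classes. Its leading genes were Prr5l, Pex5l, Tspan2 and St18. It carried oligodendrocyte and endothelial markers together, as doublets do, so it may hold doublets that were not removed. The cluster held 2.05% of kept cells in trap 2 (1.77 to 2.35), against 1.51% (1.30 to 1.74) and 0.7996% (0.627 to 1.00) in the controls. Trap 2 lay above control 1 by less than the controls differed.

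Haemoglobin RNA was higher in the trap library in oligodendrocyte-like, astrocyte-like, microglia-like and endothelial-like cells. Free RNA of lysed red blood cells would lie thinly over many cells, but at most 5.16% of the cells of any of these classes of trap 2 held a haemoglobin UMI, where an even spread over endothelial-like cells would reach 99.98%. Cells joined to red blood cells stay open: the test set for them, that the 5% of cells with the most haemoglobin hold much of it (at least 99.98% in each class), could not come out otherwise with so few positive cells. In oligodendrocyte-like cells 6 cells held 97.8% of it and in astrocyte-like cells 7 held 97.54%, and with more doublets removed the log2 change of Hbb-bs in microglia-like cells turned from 3.37 to -0.65. Whether more red blood cells stayed in the tissue of these mice for a biological or a technical reason, such as the perfusion, was not tested.

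Genes with short transcripts were higher in the trap library than in the mean of the controls. Those with a median coding transcript of at most 600 nt lay above expression-matched genes by a median of 0.16 log2 over the 5 main classes (0.12 to 0.22), so a different recovery of short cDNA between libraries may be the cause, although the bounds set for it, 0.2 in every class or at most 0.1 in 3 of them, were both missed. Short genes also differed between the controls against the order of the mitochondrial share: control 2, whose cells had the lowest share, lay above control 1 by 0.20 (0.11 to 0.24), in 5 of 5 classes above the range of matched lists. At a mitochondrial maximum of 5%, however, the excess in trap 2 was 0.13 (-0.03 to 0.17), and 3 of 5 classes lay above that range, so a higher mitochondrial share of the cells stays open too. Among the called genes that are short are Rps29, Rpl38, Rps28 and Rps27 in astrocyte-like cells, and Rps27 (345 nt) and Crip1 (509 nt) in OPC-like cells. Mt2 (449.5 nt) and Mt3 (477 nt) are short genes too. An effect of the trap on these genes was not tested apart from the library.

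Agt, Tafa1, Angpt1 and Nxn were lower in astrocyte-like cells of the trap library. A different mix of the 2 astrocyte clusters could lower them, because cluster 3, which Agt leads, was less frequent in trap 2. Within the clusters the median log2 change of the 4 genes was -0.40 in cluster 2 and -0.63 in cluster 3, against -0.77 in the whole class, and the lower ratio to the whole class, 0.523, lay between the bounds set. The values argue against the mix as the whole cause: it alone gives a median change of -0.146, and each of the 4 genes lay below both controls within both clusters by more than the controls differed. A shift within the clusters and a response of astrocytes to the trap stay open, although Tafa1 in astrocyte-like cells turned to 0.54 at a mitochondrial maximum of 5%.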

How the results depend on the processing

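Of the settings below, 7 were chosen after the result was seen: the doublet number set from all barcodes, the mitochondrial maximum of 20%, the resolutions for gene tests, the cells with haemoglobin left out, microglia cluster 1 alone, the denominator without unnamed clusters, and every setting for interactions and less frequent classes.

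No paired analysis was possible because the groups share only the replicate number 2. Leaving out a control leaves 1 library against 1, so those values have no test. The trap group is 1 library, and the gene tests rest on the spread of 2 controls, shared partly or wholly across genes. A difference of this pool of mice thus cannot be told from an effect of the trap. Of 4056 comparisons of 277 results with another setting, 3453 counted as the same, 330 as weaker, 179 as stronger, 78 as moved and 16 as reversed. Of those counted as the same, 270 left out control 1 and 268 control 2, so they had no call to keep. A share counted as the same when its log2 ratio moved by less than the SD of the controls. That SD is larger where the controls differ more, as for microglia-like cells, so such shares pass more easily. Leaving out 1 of 2 controls moves a ratio by less than this SD unless they differ many-fold. For shares that label could then hardly come out otherwise. The tally leaves out camera with an estimated correlation, fry and the tests with a control as the lone library. Fewer changes could be found in OPC-like cells: those of trap 2 held 805998 UMIs, and 22% of simulated 2-fold changes were found there, against 64% in oligodendrocyte-like cells. Their biological coefficient of variation between libraries was larger too (0.139 against 0.0804), so the part of depth was not tested apart. Where a setting gave 0 genes by edgeR, DESeq2 and limma-voom were not run with it. For every change given in the next paragraphs the cause was not tested.

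With the usual settings edgeR called 5 genes in oligodendrocyte-like, 11 in OPC-like, 37 in astrocyte-like, 114 in microglia-like and 6 in endothelial-like cells. DESeq2 size factors gave 33 in OPC-like cells, 11 of them the same genes. Scaling by library totals gave 0 in oligodendrocyte-like and 0 in endothelial-like cells by edgeR, with 1047 and 524 genes at an unadjusted p under 0.05; DESeq2 called 5 and 1 there and limma-voom 7 and 12 with their own scaling. No gene filter gave 203 in oligodendrocyte-like, 65 in OPC-like, 116 in astrocyte-like, 17 in microglia-like and 44 in endothelial-like cells. A mean of at least 20 CPM gave 0 in oligodendrocyte-like cells by edgeR (487 at an unadjusted p under 0.05; DESeq2 5 and limma-voom 7 with the usual filter). It gave 1 in OPC-like, 2 in astrocyte-like, 1 in microglia-like cells and 186 against 330 in the less frequent classes. Doublets kept gave 11 in oligodendrocyte-like, 22 in OPC-like and 0 in endothelial-like cells by edgeR (558 at an unadjusted p under 0.05; DESeq2 1 and limma-voom 12 with doublets removed). The cause was not tested.

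A mitochondrial maximum of 5% gave 2 genes in oligodendrocyte-like, 41 in OPC-like, 23 in astrocyte-like, 17 in microglia-like and 10 in endothelial-like cells. It left fewer than 50 microglia-like cells in trap 2, under the limit used at the usual settings. A maximum of 20% gave 98 in oligodendrocyte-like, 66 in astrocyte-like, 59 in microglia-like and 0 in OPC-like cells by edgeR (502 at an unadjusted p under 0.05; DESeq2 1 and limma-voom 67 at 10%). At least 1000 UMIs per cell gave 70 in OPC-like cells. Counts thinned to the smallest library gave 120 in oligodendrocyte-like, 11 in astrocyte-like, 73 in microglia-like, 34 in endothelial-like and 0 in OPC-like cells by edgeR (315 at an unadjusted p under 0.05; DESeq2 1 and limma-voom 67 without thinning). Without the genes of free RNA the count was 57 in OPC-like and 1 in endothelial-like cells, and without cells with haemoglobin 21 in astrocyte-like and 12 in endothelial-like cells. The doublet number set from all barcodes gave 83 in oligodendrocyte-like, 80 in OPC-like and 5 in astrocyte-like cells. Resolution 0.5 gave 36 in oligodendrocyte-like and 20 in astrocyte-like cells. Resolution 2 gave 192 in oligodendrocyte-like, 2 in OPC-like, 103 in astrocyte-like and 52 in microglia-like cells, and microglia cluster 1 alone gave 30. The Wald test of DESeq2 called 1 in OPC-like, 3 in astrocyte-like, 1 in endothelial-like and 9 in the less frequent classes. In microglia-like cells it called 0, with 90 genes at an unadjusted p under 0.05. limma-voom called 67 in OPC-like, 12 in endothelial-like and 62 in microglia-like cells. The cause was not tested.

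camera with a preset correlation called 8 lists in oligodendrocyte-like, 14 in OPC-like, 7 in astrocyte-like, 9 in microglia-like and 8 in endothelial-like cells. With an estimated correlation it called 0 in each of the 5 classes, with 2 of 146 tests at an unadjusted p under 0.05 and a smallest adjusted p of 0.959. fry called 0 in each of the 5 classes, with 7 of 146 tests at an unadjusted p under 0.05 and a smallest adjusted p of 0.507. A mean of at least 20 CPM gave 5 lists in oligodendrocyte-like and 5 in endothelial-like cells. A mitochondrial maximum of 5% gave 3 in oligodendrocyte-like, 3 in astrocyte-like, 1 in microglia-like and 5 in endothelial-like cells, and the doublet number set from all barcodes gave 12 in astrocyte-like cells. The cause was not tested.

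The difference between trap 2 and the controls in oligodendrocyte-like cells departed from that in astrocyte-like cells in 38 genes, of microglia-like cells in 14 and of endothelial-like cells in 9. With doublets kept the counts were 0 (636 at an unadjusted p under 0.05 by edgeR, the only tool run on interactions), 1 and 4. A mitochondrial maximum of 20% gave 16 for astrocyte-like and 0 for endothelial-like cells by edgeR (726 at an unadjusted p under 0.05). One of 5% gave 12 and 0 (515 at an unadjusted p under 0.05). DESeq2 size factors gave 10 for astrocyte-like cells, 5 with the higher and 5 with the lower log2 difference in oligodendrocyte-like cells against 25 and 13 before. They gave 3 and 18 for microglia-like cells against 4 and 10, and 4 and 8 for endothelial-like cells against 4 and 5. Library totals gave 2 and 4 for endothelial-like cells. The cause was not tested.

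The log2 ratio of the share of cells in trap 2 to that in the controls was -0.06 for OPC-like, -0.17 for astrocyte-like, -0.13 for endothelial-like, -0.58 for microglia-like and 0.03 for oligodendrocyte-like cells. Doublets kept gave 0.57 for OPC-like cells, and in the lineage 0.48 for OPC-like (against -0.12) and -0.0430 for oligodendrocyte-like cells (against -0.0135). A mitochondrial maximum of 20% gave 0.15 for OPC-like, 0.0705 for astrocyte-like and -0.12 for microglia-like cells, and 0.0947 for new oligodendrocyte-like cells in the lineage (against 0.46). A maximum of 5% gave -1.05 for astrocyte-like, -0.39 for endothelial-like, -2.50 for microglia-like and -0.49 for oligodendrocyte-like cells, and in the lineage 1.08 for new oligodendrocyte-like and -0.41 for oligodendrocyte-like cells. With the denominator without microglia-like cells the neuron-like ratio moved from 0.95 to 0.85 and the border macrophage-like ratio from -0.12 to -0.22, and without unnamed clusters the neuron-like ratio moved to 1.02. Leaving out a control moved the share ratio from -0.10 to 0.17 for oligodendrocyte-like and from -0.17 to 0.06 for OPC-like cells. The cause was not tested.

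Some log2 changes reversed. At a mitochondrial maximum of 5%, where trap 2 kept 53 astrocyte-like and 25 microglia-like cells, Tafa1 in astrocyte-like cells was at 0.54, against -0.75 at 10%, and Hbb-bs in microglia-like cells at -4.52, against 3.37. Hba-a1 in microglia-like cells was at -3.00 (against 3.76), Hba-a2 at -2.19 (3.72), Csmd1 in microglia-like cells at -7.67 (1.08), Snhg11 at -0.40 (0.90) and mt-Nd4l in microglia-like cells at -0.0927 (0.51). With the doublet number set from all barcodes, Hbb-bs in microglia-like cells was at -0.65, Hba-a1 at -0.49, Hba-a2 at -1.05 and Hbb-bt in microglia-like cells at -1.79 (against 4.94). Without cells with haemoglobin, Hbb-bs in endothelial-like cells was at -0.0408, against 2.82. Leaving out each control, the median of the astrocyte list in oligodendrocyte-like cells ranged from -0.00446 to 0.51, of the myelin list in OPC-like cells from -0.0283 to 0.70 and of the cytosolic ribosome list in OPC-like cells from -0.00863 to 0.15. The median of the list cytosolic ribosome in astrocyte-like cells ranged from -0.0535 to 0.0623. The cause was not tested.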

Other observations

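All counts and shares given next, and the choice of these genes and clusters, were chosen after the result was seen.

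Vegfc UMIs in endothelial-like cells numbered 336, 251 and 149 in control 1, control 2 and trap 2, which is 77.5 (69.5 to 86.3), 68.4 (60.2 to 77.5) and 52.2 (44.2 to 61.3) CPM without TMM scaling, with 95% Poisson intervals that cover counting error only. Vegfa, the main growth factor of blood vessels, had 40, 34 and 18 UMIs in the same cells. That is 9.23, 9.27 and 6.31 CPM, with overlapping intervals. Flt1, the gene of VEGFR-1, stood at 6274, 6085 and 5649 CPM. Vegfc was not lower in every class: in OPC-like cells it stood at 11.3, 16.0 and 25.6 CPM, from 14, 16 and 21 UMIs.

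A cluster led by Top2a, Hmgb2 and Mki67, genes of dividing cells, also carried neuroblast markers and stayed without a name. It held 0.923% of kept cells in trap 2 (0.740 to 1.14), against 0.595% (0.468 to 0.745) and 0.591% (0.445 to 0.771) in the controls. A cluster led by the vessel-wall genes Rgs5 and Vtn and also rich in endothelial markers held 3.24%, 3.23% and 3.07% in trap 2, control 1 and control 2. A cluster of immune cells led by Cd74 and the MHC class II genes H2-Eb1 and H2-Ab1 held 0.350% in trap 2 (0.241 to 0.491), against 0.460% and 0.515%. Among neuron-like cells, cluster 8, led by Tafa1 and Kcnip4, held 5.00% of kept cells in trap 2 (471 cells) against 2.83% (357) and 1.95% (178). Cluster 28, led by Rarb and Penk, genes of striatal neurons, held 1.02% (96) against 0.468% (59) and 0.361% (33). Cluster 19 was higher too, at 1.79% against 0.762% and 1.19%. Clusters 31 (0.456% against 0.333% and 0.504%) and 36 (0.350% against 0.0952% and 0.405%) lay between the controls.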
